A study of Mus musculus with 14 samples.

How the data were processed

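Gene expression was measured on Affymetrix Mouse Genome 430 2.0 arrays in 14 samples of secondary neurospheres from CD-1 mice, 1 array per sample. Neurospheres are floating clusters that neural stem and progenitor cells form in culture, together with their progeny. The adult groups were the neocortex, the striatum and the subventricular zone (SVZ), with 3 samples each. The embryonic groups, from embryonic day 14.5, were the dorsal forebrain and the ventral forebrain with 2 samples each and the spinal cord with 1.

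The deposited expression values were linear intensity values per probe set. On every array their mean after trimming 2% of the values from each tail was 1500, while the median signal ran from 222.1 to 334.8. The labels describe a GeneSpring analysis normalized to the median, which these values do not show, and they do not state how probes were summarised. Deposited detection calls of another kind, present, marginal or absent per probe set and array, came from a second table whose columns name the region and stage of each array. These calls were used by group only, because the columns do not name the sample. The share of probe sets called present was 60.2% to 65.7% in the adult and embryonic forebrain groups and 68.6% in the spinal cord. The lowest signal of a probe set called present on all arrays was 22.6 to 40.4 between samples. Signals near that level are background, and the number of arrays limits the precision of every value.

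Of 45101 probe sets, 64 controls were left out. Of the remaining 45037, 34945 were paired with exactly 1 gene symbol in the platform annotation, 932 with several genes, and 9160 were not in the annotation table. The gene identifiers of 34754 probe sets matched the RefSeq gene table of GRCm38.p6, used for names only, and 0 symbols changed on the match. A probe set was kept when called present on at least 2 arrays, which left 35211 probe sets and 28545 with 1 symbol. Each gene was represented by its kept single-gene probe set with the highest mean over the 14 samples, giving 14716 genes, of which 7532 had over 1 kept probe set. For 1514 genes the chosen probe set ends in a suffix that marks probes shared between transcripts. No column belonged to another series.

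The values were transformed as log2 of the signal plus 16. The comparisons used limma 3.58.1 in R 4.3.3 with a mean per group over all 14 samples, empirical Bayes moderation with a trend on the mean level, two-sided tests, and Benjamini-Hochberg adjustment over 14716 genes at an adjusted p of 0.05. The groups shared a spread estimated with 8 residual degrees of freedom. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between samples. There were 6 comparisons: adult against embryonic forebrain (mean of 3 adult group means minus mean of 2 embryonic forebrain group means), the 3 pairs of adult regions, embryonic dorsal against ventral forebrain, and the difference between the adult neocortex-striatum contrast and the embryonic dorsal-ventral contrast. The 2-fold rule of the study design was applied per adult region without a test. The spinal cord sample was compared with the 4 embryonic forebrain samples without a test.

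The design, the gene lists and most alternatives were fixed before the data were examined. There were 19 gene lists with 314 genes, of which 267 were tested: pallial patterning, subpallial patterning, Hox genes, neural stem and progenitor, astrocyte, oligodendrocyte lineage, neuron, cell cycle, cyclin-dependent kinase inhibitors, fetal growth and imprinted, MHC class I and interferon, reactive glia and extracellular matrix, Notch pathway, hedgehog pathway, mural and fibroblast, endothelial, microglia, ependymal, and sex-linked. Lists were tested with limma's camera at a preset correlation of 0.01, and adjusted over all 114 list tests. Both an estimated correlation and fry were run as alternatives. Of 51 list calls with the preset correlation, 0 held with an estimated correlation, so each list call below carries that second adjusted p.

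Genes are named by this rule: per comparison, the 10 with the largest increase and the 10 with the largest decrease past the threshold whose sides do not overlap in any sample, without clone or predicted names, and any member of a list. For the spinal cord the rule took the 10 largest differences either way outside the range of the 4 forebrain samples and detected on the higher side. No other probe set of a named gene passed the threshold in the opposite direction. Changes are given as log2 differences with their standard error (SE). A fold is written as at least N-fold when the gene was absent on every array of the lower side. For this bound, lower-side signals were raised to at least the lowest signal of a probe set called present on all arrays. Some genes above that level were also absent, such as Ccl3 at a mean of 6.11 (log2) in SVZ spheres. The bound is therefore not a strict lower limit for genes called absent. List medians use the fitted values. With such genes set at their bound, the medians of the microglia list became 1.32 for adult against embryonic forebrain, 4.37 for neocortex against SVZ and 0.26 for dorsal against ventral forebrain. No other list median printed for the 6 comparisons moved by more than 0.1.

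The scripts were tested on simulated data with 200 of 14716 genes changed. For adult against embryonic forebrain 45% of 2-fold and 83% of 4-fold changes were recovered. The shares were 33% and 67% for neocortex against SVZ, and 30% and 61% for striatum against SVZ. They were 28% and 72% for neocortex against striatum, 15% and 50% for dorsal against ventral forebrain, and 9% and 29% for the difference of contrasts. Between 0.99% and 5.88% of the simulated calls were false. The simulated noise was independent between genes and between samples. Neither these shares nor the list test below therefore cover deviations shared between genes or between same-numbered samples. In a simulated neocortex against SVZ comparison, an astrocyte list raised by 0.5 (log2) had an adjusted p of 0.0295 with the preset correlation and 0.53 with the estimated correlation.

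The labels number the samples within each group without saying what a number shares. Deviations from the group means were correlated across genes between same-numbered neocortex and striatum samples, with r of 0.30, 0.13 and 0.14 for numbers 1 to 3. By the rule that every pair exceeds 0.1, these numbers pair the neocortex and striatum samples. The array codes in the table of detection calls also repeat across the 3 adult regions, without saying what they share and without naming the samples. The fit with the sample number as a block is given beside that comparison where it moved a call. Same-numbered dorsal and ventral embryonic samples had an r of 0.61, a single value. The block's gene counts are also given beside the comparisons that hold the dorsal-ventral contrast.

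Alternatives covered the pseudocount, normalization, presence filter, probe sets per gene, variance model, samples in the fit, sample number as a block, and each sample left out in turn. Some were added only after the data had been seen, as stated in the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.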

Results

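The series holds array profiles of 14 neurosphere samples from mouse brain and spinal cord. The 9 adult samples came from the neocortex, the striatum and the SVZ, a lasting site of neurogenesis in the adult forebrain, with 3 samples per region. The 5 embryonic samples came from the dorsal forebrain (2), the ventral forebrain (2) and the spinal cord (1). Every array had the same trimmed mean signal of 1500. Median signals were 270.3 to 278.7 in neocortex, 234.9 to 273.6 in striatum, 222.1 to 244.6 in SVZ, 260.8 to 289.9 in embryonic forebrain, and 334.8 in spinal cord. The median standard deviation of a gene within a group (log2) was 0.264 in neocortex, 0.246 in striatum and 0.241 in SVZ. It was 0.336 in dorsal and 0.351 in ventral embryonic forebrain, where the sample numbered 2 of each region stood apart from the sample numbered 1. In both regions sample 2 had higher medians of the endothelial list, by 3.87 (dorsal) and 3.19 (ventral), and of the microglia list, by 2.98 and 1.66. In the same samples the oligodendrocyte lineage list was lower, with differences of -2.25 and -0.61.

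**Figure D1:**
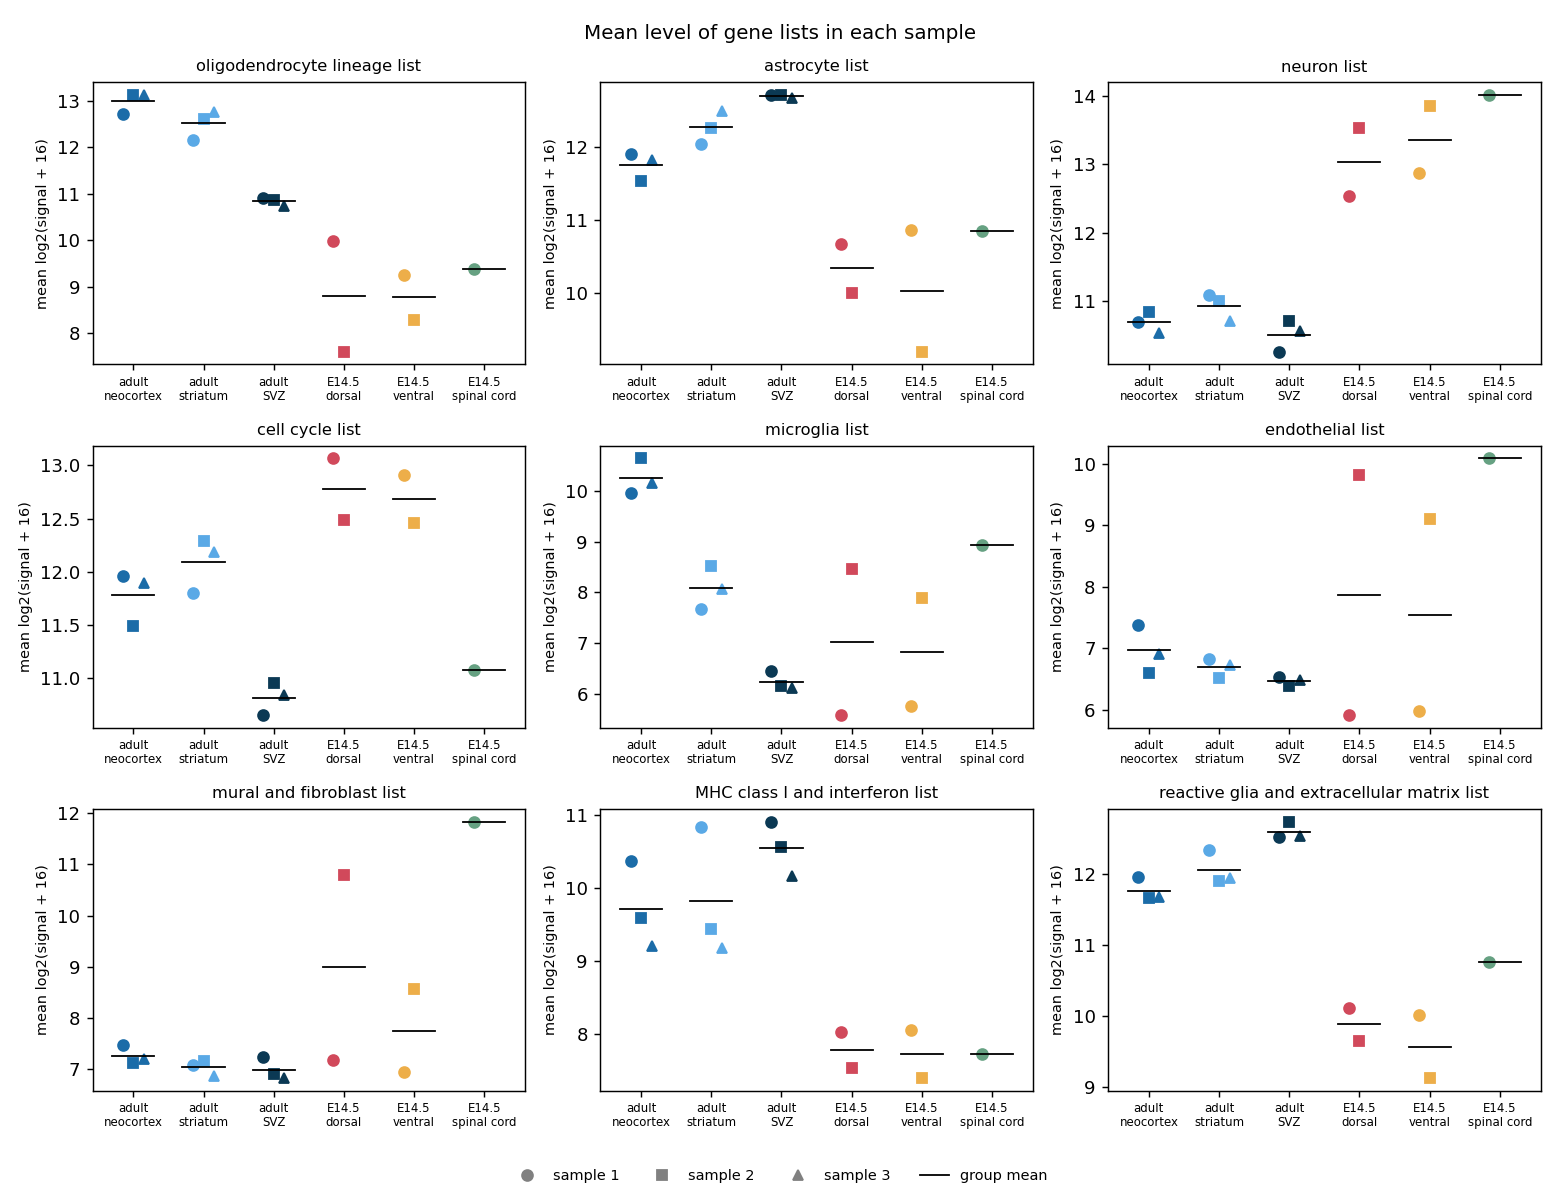
Mean log2(signal + 16) of 9 gene lists in each of the 14 samples, by group, with a marker per sample number and a line at each group mean. Microglia list means lie between 9.96 and 10.65 in the 3 adult neocortex samples and between 6.12 and 6.44 in the 3 SVZ samples.

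Adult and embryonic forebrain spheres were compared to find genes that mark spheres of adult origin, an aim stated in the design. Mbp, which encodes myelin basic protein, was higher by 7.56 ± 0.13 (log2, SE, n = 9 and 4, limma adjusted p = 1.1e-11). Mag, the myelin-associated glycoprotein, was at least 73.2-fold higher (adjusted p = 6.51e-09). Il33, an alarmin cytokine, was higher by 8.43 ± 0.20 (adjusted p = 1.64e-10), and S100b, a calcium-binding protein of glia, by 6.45 ± 0.39. Serpina3n, a protease inhibitor typical of reactive astrocytes, was at least 68.1-fold higher. Neurod6 and Tbr1, transcription factors of cortical projection neurons, were lower in adult spheres, Neurod6 at least 99.8-fold and Tbr1 with a log2 difference of -7.25 ± 0.47. Both were higher in the embryonic samples numbered 2 than in those numbered 1, Neurod6 by 2.30 (dorsal) and 2.47 (ventral) and Tbr1 by 2.295 and 1.995. Dcx, a microtubule protein of migrating neurons, differed by -6.67 ± 0.48. Xist, the RNA that silences an X chromosome, was at least 247-fold lower in adult spheres. It was called present in 0 of 9 adult and in all 4 embryonic forebrain samples, so sex makeup and age cannot be told apart in this comparison. Other genes with large differences were Mobp, Mal, Aox1, Tnfaip2 and Lcn2, all higher, and Glra2, Epha3, Neurod2, Miat and Elmod1, all lower. Beta globin Hbb-b2 was at least 39.2-fold lower in adult spheres, and among embryonic samples its log2 level was 14.34 and 14.41 in the samples numbered 2 against 7.50 and 7.99 in those numbered 1.

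In the oligodendrocyte lineage list 14 of 18 measured genes were higher in adult spheres (16 when adjusted over the list alone), 0 were lower, and the median was 2.73. They included Mog by 4.82 ± 0.50, Cldn11 by 4.34 ± 0.38 and Sox10, a lineage transcription factor, by 3.66 ± 0.74. From embryonic sample 1 to sample 2, Sox10 differed by -5.42 (dorsal) and -1.79 (ventral), Cldn11 by 1.98 and -2.20, and Mog by 2.56 and 2.36. The list's camera adjusted p was 1.66e-07, and adjusted p = 0.255 with an estimated correlation. In the astrocyte list 13 of 17 were higher and 0 lower, by the same count over the list alone, with a median of 1.29. The list's adjusted p was 1.15e-05, and adjusted p = 0.303 with an estimated correlation. Its members included Gfap, the astrocyte intermediate filament, by 5.70 ± 0.68, the water channel Aqp4 by 4.08 ± 0.61 and Apoe by 4.02 ± 0.25. These glial lists were lower in the embryonic samples numbered 2. Without the samples numbered 2 and the spinal cord, an alternative chosen after seeing the data, the oligodendrocyte lineage median was 1.83 and the astrocyte median 0.54. Without the samples numbered 1 they were 4.41 and 1.86.

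The reactive glia and extracellular matrix list had 13 of 17 genes higher and only Fn1 lower, also over the list alone, with a median of 2.78. The median was 1.82 without the embryonic samples numbered 2 and 2.56 without those numbered 1, where 3 genes were lower. The call of Fn1 was lost without dorsal or ventral sample 2 (limma adjusted p = 0.0623 and 0.0654). The list's adjusted p was 5.41e-05, and adjusted p = 0.12 with an estimated correlation. Cd44, a hyaluronan receptor, was higher by 4.06 ± 0.81 and the ferroxidase Cp by 4.69 ± 0.47. From embryonic sample 1 to sample 2, Cd44 differed by -4.78 (dorsal) and -4.15 (ventral), and Cp by 0.085 and -3.27. In the MHC class I and interferon list 14 of 18 were higher (15 over the list alone), with a median of 2.24, an adjusted p of 7.55e-06, and adjusted p = 0.287 with an estimated correlation. Psmb8, an immunoproteasome subunit, was higher by 4.18 ± 0.41 and H2-D1, a class I heavy chain, by 2.44 ± 0.30. In the microglia list 6 of 14 were higher, by either adjustment, with a median of 1.47, an adjusted p of 0.0298, and adjusted p = 0.665 with an estimated correlation. Cd68, a lysosomal protein of phagocytes, was higher by 3.15 ± 0.21. The microglia median was 2.86 without the embryonic samples numbered 2 and -0.003 without those numbered 1. The adult regions also differed in the mean of this list. It was 9.96 to 10.65 in neocortex, 7.66 to 8.52 in striatum and 6.12 to 6.44 in SVZ samples. The SVZ values lay within the embryonic forebrain range of 5.58 to 8.45, so the higher level was not shared by all adult spheres.

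Of 17 neuron genes 15 were lower in adult spheres and only Nefl was higher, also over the list alone, with a median of -1.85, an adjusted p of 8.3e-07, and adjusted p = 0.294 with an estimated correlation. Tubb3, a neuronal tubulin, differed by -4.21 ± 0.38 and the synaptic vesicle protein Syt1 by -5.59 ± 0.49. All 23 cell cycle genes were lower, also over the list alone, with a median of -1.15, an adjusted p of 3.7e-09, and adjusted p = 0.371 with an estimated correlation. They included the proliferation marker Mki67 (-0.91 ± 0.13), topoisomerase Top2a (-1.44 ± 0.15) and the mitotic kinesin Kif11 (-1.90 ± 0.19). The smallest difference, that of Rrm2 (-0.47), was not past the threshold without the dorsal or the ventral sample numbered 1 (limma adjusted p = 0.0967 and 0.084), and had the opposite sign with the spinal cord among the embryonic groups (0.12).

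Patterning genes were mostly lower in adult spheres. In the pallial list 14 of 19 were lower and only Wnt7b was higher, also over the list alone, with a median of -1.96, an adjusted p of 0.000131, and adjusted p = 0.433 with an estimated correlation. Emx1 differed by -1.96 ± 0.36 and Gli3, a repressor of the hedgehog pathway, by -2.34 ± 0.28. The call of Wnt7b was lost without dorsal sample 1 (limma adjusted p = 0.0773). In the subpallial list 12 of 17 were lower and Gsx1 and Nkx6-2 were higher, also over the list alone, with a median of -1.89, an adjusted p of 0.0163, and adjusted p = 0.503 with an estimated correlation. Dlx5, a transcription factor of inhibitory neurons, differed by -4.47 ± 0.49, and Lhx6 was at least 35.1-fold lower. The embryonic samples numbered 2 had higher medians of both lists than those numbered 1. Without the samples numbered 2 the pallial median was -1.26 and the subpallial median -1.04, and without those numbered 1 they were -2.83 and -2.40. In the fetal growth and imprinted list 9 of 14 were lower (11 over the list alone) and Hmga2 was higher. Its median was -0.97, its adjusted p was 0.000994, and adjusted p = 0.252 with an estimated correlation. The fetal growth median was -0.80 without the embryonic samples numbered 2 and -1.99 without those numbered 1. Grb10, an imprinted growth inhibitor, differed by -4.26 ± 0.28 and the RNA-binding protein Igf2bp3 by -2.93 ± 0.16.

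The other lists did not pass as lists. In the Notch list 7 of 15 genes were lower and 2 higher (8 and 4 over the list alone, camera adjusted p = 0.0864), with Hes5, a Notch target, at -3.22 ± 0.17. Of 10 hedgehog genes 4 were lower and 1 higher by either adjustment (0.156). Of 15 mural and fibroblast genes 4 were lower by either adjustment (0.132), and 1 of 10 endothelial genes was lower (0 over the list alone, 0.356). The call of that gene, Tie1, was lost without dorsal or ventral sample 2 (limma adjusted p = 0.144 and 0.0823), and that of Ptch1, the higher hedgehog gene, without dorsal sample 2 (0.0649). These lists turned on which embryonic samples were kept. Without the samples numbered 2, 3 mural and fibroblast genes were higher and 4 lower (median -0.046), and 2 endothelial genes were higher and 0 lower (0.69). Without those numbered 1, 11 mural and fibroblast genes were lower and 1 higher (-2.92), and 9 endothelial genes were lower (-2.87). Among 7 cyclin-dependent kinase inhibitors, Cdkn1a, Cdkn2a and Cdkn2b were higher and Cdkn1b and Cdkn1c lower by either adjustment (0.721). The call of Cdkn1b was lost without neocortex or striatum sample 2 or 3, SVZ sample 2, or dorsal or ventral sample 2. Cdkn2b was higher by 4.52 ± 0.65, and from embryonic sample 1 to sample 2 it differed by -3.71 (dorsal) and -3.66 (ventral). Of 19 neural stem and progenitor genes 5 were lower, and Vim and Hmga2 were higher, by either adjustment (0.615), with a median of -0.17. Without the samples numbered 2 the counts were the same (median -0.36), and without those numbered 1, 6 genes were lower and 7 higher (0.22). Among the lower genes Nr2e1, which is a forebrain gene, was higher in adult spheres by 1.63 with the spinal cord among the embryonic groups. Of 12 ependymal genes 3 were higher and 3 lower by either adjustment (0.945), with a median of -0.098 and a mean of 0.10. Of 8 Hox genes 0 passed by either adjustment (0.872). The sex-linked list (0.865) had a median of 1.82 and a mean of -0.53, since its Y-linked members Eif2s3y, Kdm5d and Uty were higher and Xist lower by either adjustment. The calls of Kdm5d and Uty were lost without dorsal sample 1, and that of Kdm5d also without dorsal sample 2.

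Over all genes, 7275 of 14716 differed past the threshold, with 3571 higher and 3704 lower in adult spheres. Of these, 1981 were higher and 1788 lower by at least 2-fold. The fit takes the 4 embryonic forebrain samples as independent, while same-numbered dorsal and ventral samples deviated together (r of 0.61). If such samples share a preparation, the SEs of this comparison are too small and its count too high. The count was 5649 without the embryonic samples numbered 2 and the spinal cord, and 7902 without the embryonic samples numbered 1, both chosen after seeing the data. Of 184 named calls, 150 held without each sample in turn, and most lost calls went with an embryonic forebrain sample numbered 2.

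**Figure D2:**
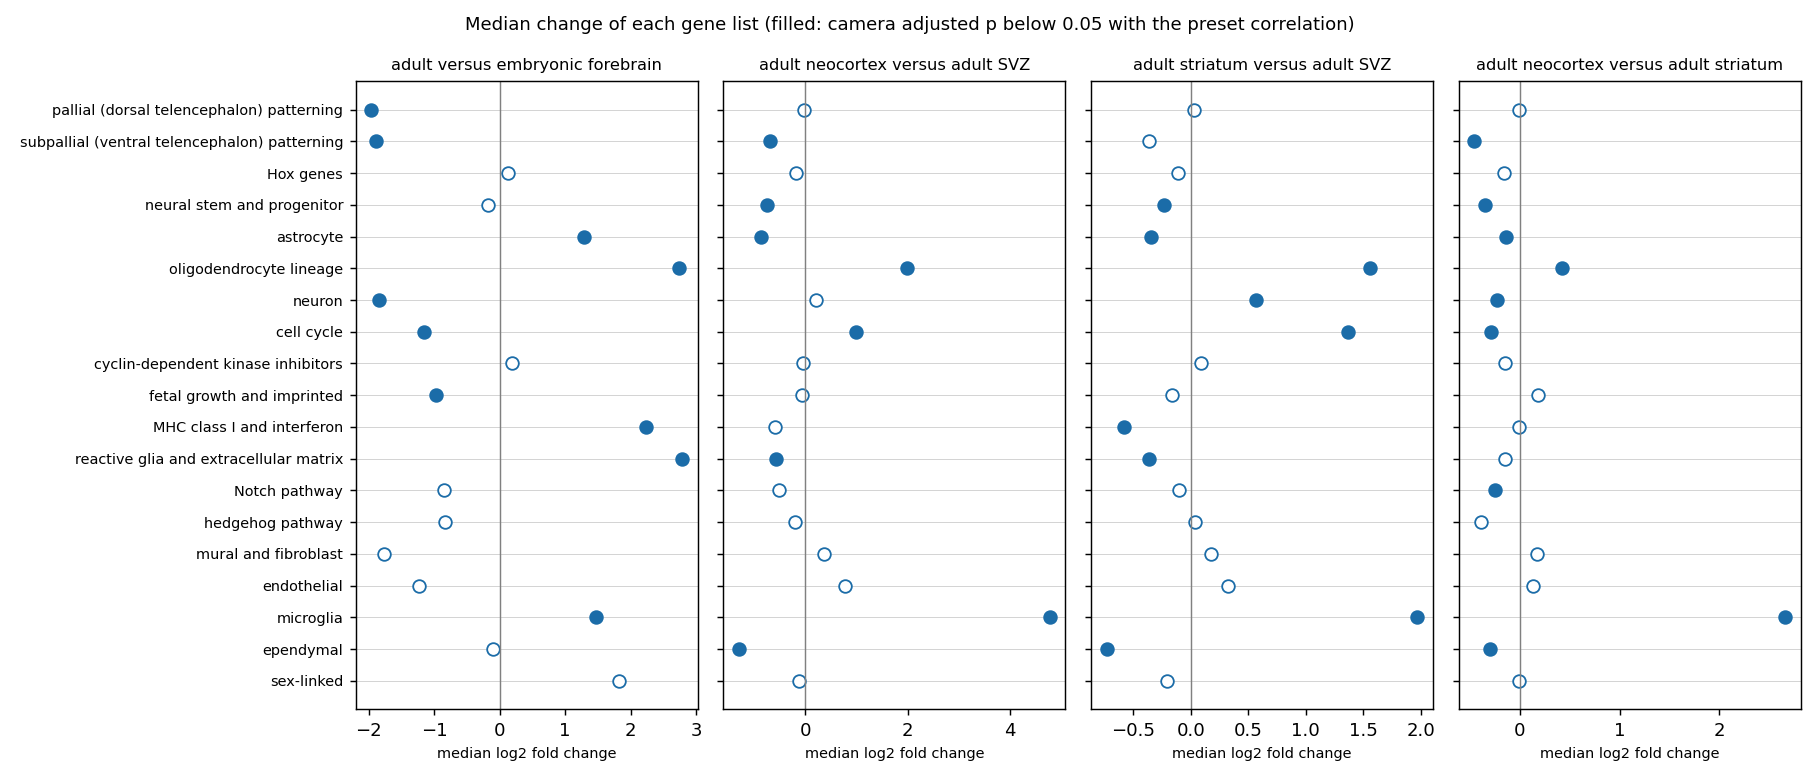
Median log2 fold change of each of the 19 gene lists in 4 comparisons, filled where the camera adjusted p passed with the preset correlation. The horizontal scales differ between panels, and the microglia list has its largest median, 4.77, in adult neocortex against SVZ.

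Adult neocortex spheres were set against SVZ spheres to ask how spheres from outside the neurogenic zone differ from those within it. Mmp12, the macrophage elastase, was at least 562-fold higher (limma adjusted p = 5.14e-06, n = 3 and 3). Clec4d, a lectin receptor of myeloid cells, was at least 231-fold higher and the chemokine Ccl3 at least 154-fold higher. Ctss, a lysosomal protease, was higher by 7.70 ± 1.06 (log2, SE) and the complement receptor C3ar1 by 7.52 ± 0.82. Csf1r, the receptor that microglia need to survive, was at least 105-fold higher (adjusted p = 0.00892). Genes lower in neocortex spheres included the casein gene Csn3 (-6.65 ± 0.73), the secretory granule protein Scg2 (-5.10 ± 0.88) and Esm1, a secreted proteoglycan (-4.89 ± 0.79). Vdr, the vitamin D receptor, was at least 12.9-fold lower. Other top genes were Cd53, Cd5l, C5ar1 and Il7r, all higher, and Cyp2d22, Car4, Col12a1, Car9 and Calb2, all lower. The calls of Car9 and Calb2 were lost without neocortex sample 2 or 3 or SVZ sample 1 or 2, and that of Car9 also without SVZ sample 3.

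In the microglia list 10 of 14 genes were higher in neocortex (11 over the list alone) and 0 lower, with a median of 4.77, a camera adjusted p of 1.51e-08, and adjusted p = 0.277 with an estimated correlation. They included the signalling adaptor Tyrobp by 6.58 ± 0.75 and the complement genes C1qb by 6.34 ± 1.35 and C1qc at least 28.4-fold. Itgam, Cx3cr1, P2ry12 and Tmem119 were the members not called over all genes. In the oligodendrocyte lineage list 8 of 18 were higher (10 over the list alone) and 0 lower, with a median of 1.99, an adjusted p of 1.3e-07, and adjusted p = 0.255 with an estimated correlation. Mog was higher by 4.78 ± 0.69, Ugt8a, an enzyme of myelin lipid synthesis, by 4.06 ± 0.37 and Mbp by 1.64 ± 0.18. In the cell cycle list 16 of 23 were higher (20 over the list alone) and 0 lower, with a median of 0.98, an adjusted p of 1.83e-10, and adjusted p = 0.327 with an estimated correlation. Kif11 was higher by 1.92 ± 0.25 and the replication helicase subunit Mcm5 by 1.57 ± 0.22.

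In the neural stem and progenitor list 7 of 19 were lower (8 over the list alone) and 0 higher, with a median of -0.75, an adjusted p of 2.22e-05, and adjusted p = 0.12 with an estimated correlation. Sox1 differed by -2.24 ± 0.44, Hes5 by -1.72 ± 0.22 and Nr2e1, a nuclear receptor that maintains neural stem cells, by -1.38 ± 0.26. In the astrocyte list 6 of 17 were lower (7 over the list alone) and S100b was higher, with a median of -0.88, an adjusted p of 0.000287, and adjusted p = 0.401 with an estimated correlation. Gfap differed by -4.19 ± 0.92 and the glutamate transporter Slc1a2 by -1.42 ± 0.18. In the ependymal list, which marks ciliated cells, 4 of 12 were lower (7 over the list alone), with a median of -1.30, an adjusted p of 0.000115, and adjusted p = 0.24 with an estimated correlation. Rfx2, a transcription factor of ciliogenesis, differed by -1.75 ± 0.29. In the reactive glia and extracellular matrix list 3 of 17 were lower, also over the list alone, with a median of -0.57, an adjusted p of 0.00641, and adjusted p = 0.252 with an estimated correlation. Timp1, a protease inhibitor, differed by -3.95 ± 0.79. In the subpallial list Six3 and Meis2 were lower (3 genes over the list alone) and Nkx6-2 higher, with a median of -0.69, an adjusted p of 0.0365, and adjusted p = 0.558 with an estimated correlation. The call of Meis2 was lost without neocortex sample 2 or 3. Six3, a transcription factor of the ventral forebrain, differed by -3.46 ± 0.39. In the pallial list, which did not pass (0.81), Emx2, Lhx2 and Wnt7b were lower and Dmrt3 and Dmrta1 higher by either adjustment, with a median of -0.026 and a mean of 0.22. The call of Wnt7b was lost when any neocortex or SVZ sample, or striatum sample 2 or 3, was left out.

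In all, 1852 of 14716 genes passed, with 1182 (63.8%) higher in neocortex and 670 lower. With each array centred on its median the calls were 896 higher (46.2%) and 1043 lower, and the median of all genes moved from 0.0369 to -0.119. Leaving out neocortex sample 2 or 3 gave 1127 or 1043 calls, and leaving out SVZ sample 1 or 3 gave 1128 or 1103, while 66 of 91 named calls held without each sample in turn. With the 9 adult samples alone, chosen after seeing the data, 3348 genes passed, 1850 of them among the 1852.

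Striatum spheres were compared with SVZ spheres for the same question. Mmp12 was at least 57.0-fold higher (limma adjusted p = 0.000565, n = 3 and 3), Clec4d at least 20.4-fold and the cytokine receptor Il7r at least 7.89-fold. Spock1, a secreted proteoglycan, was higher by 3.69 ± 0.56 (log2, SE). Among the genes most reduced in striatum, the contractile protein Cnn1 was at least 5.52-fold lower and the relaxin-family peptide Insl5 at least 3.10-fold lower. Even on the higher side, Insl5 was called present on only 1 of 3 SVZ arrays. Other top genes were Ctss, C3ar1, Cd53, Tyrobp, C5ar1 and Mog, all higher, and Csn3, Slco1c1, Muc1, Fam210b, Stbd1, Klhl1, Calhm5 and P2ry6, all lower. All of these 14 calls were lost without at least 1 striatum or SVZ sample. Klhl1 was called present on only 1 of 3 SVZ arrays.

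In the cell cycle list 19 of 23 genes were higher in striatum (21 over the list alone) and 0 lower, with a median of 1.37, a camera adjusted p of 1.63e-22, and adjusted p = 0.24 with an estimated correlation. Kif11 was higher by 2.20 ± 0.25, Mcm5 by 1.85 ± 0.22, Ccna2, a cyclin of S phase and mitosis, by 1.68 ± 0.23 and Top2a by 1.37 ± 0.21. Of the calls in this list only those of Ccna2, Ccnb2, Cenpe, Kif11, Mcm5, Mcm6 and Top2a held without each sample in turn. In the oligodendrocyte lineage list 5 of 18 were higher (8 over the list alone) and 0 lower, with a median of 1.56, an adjusted p of 3.45e-08, and adjusted p = 0.252 with an estimated correlation. Ugt8a was higher by 3.32 ± 0.37, Mag by 2.74 ± 0.32 and Mbp by 1.29 ± 0.18. In the microglia list Ptprc and Tyrobp were higher (6 genes over the list alone), with a median of 1.97, an adjusted p of 0.00128, and adjusted p = 0.503 with an estimated correlation.

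Other list calls against the SVZ were smaller. The ependymal list had a median of -0.73, with 1 of 12 lower (3 over the list alone), an adjusted p of 0.00088, and adjusted p = 0.252 with an estimated correlation. The astrocyte list had a median of -0.35, with Apoe, Clu and Slc1a2 lower and S100b higher by either adjustment, an adjusted p of 0.00276, and adjusted p = 0.503 with an estimated correlation. Each of these gene calls was lost without striatum sample 2 or 3. The MHC class I and interferon list had a median of -0.58 with 0 genes past the threshold by either adjustment, an adjusted p of 0.0198, and adjusted p = 0.561 with an estimated correlation. Its mean was 10.84 in striatum sample 1 against 9.45 and 9.18 in striatum samples 2 and 3. In SVZ samples 1, 2 and 3 it was 10.91, 10.56 and 10.16. Reactive glia and matrix genes had a median of -0.36 with 1 lower by either adjustment, an adjusted p of 0.0214, and adjusted p = 0.277 with an estimated correlation. Neural stem and progenitor genes had a median of -0.23 with only Hes5 lower by either adjustment (-1.39 ± 0.22), an adjusted p of 0.0256, and adjusted p = 0.287 with an estimated correlation. After quantile normalization the neural stem and reactive glia lists did not pass (camera adjusted p = 0.0773 and 0.0632). Neuron genes had a median of 0.56 with Map2 higher (4 over the list alone), an adjusted p of 0.0367, and adjusted p = 0.669 with an estimated correlation.

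In all, 608 genes passed, 494 higher and 114 lower in striatum. The count fell to 84 without striatum sample 2 and 106 without striatum sample 3, and to 240, 361 and 224 without SVZ samples 1, 2 and 3. Of 54 named calls 17 held without each sample in turn. With the 9 adult samples alone, chosen after seeing the data, 1543 genes passed, 608 of them shared.

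Neocortex and striatum spheres, both from outside the SVZ, were compared with each other. Cybb, the catalytic subunit of the phagocyte oxidase, was higher in neocortex by 3.77 ± 0.42 (log2, SE, n = 3 and 3, limma adjusted p = 0.00397), and Cd68 by 2.84 ± 0.28. Slfn2, a gene of immune cells, was at least 9.76-fold higher. Six3 was lower in neocortex by a log2 difference of -3.02 ± 0.39 (adjusted p = 0.00757). These 4 were the only named calls of 18 that held without each sample in turn. The others were Selplg, Cd5l, Cd244a, Vav1, Wfdc17, Cd37, Cd300c2, Was and Fcer1g, all higher. Six3os1, the transcript opposite Six3, was lower at least 11.8-fold, and Vax1, Gria1, Ttyh1 and Wnt5b were also lower. Vax1 was called present on only 1 of 3 striatum arrays.

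In the microglia list Cd68 and Fcer1g were higher (8 of 14 over the list alone), with a median of 2.66, a camera adjusted p of 2.32e-10, and adjusted p = 0.252 with an estimated correlation. No member of 8 further lists with a list call passed over all genes, apart from Six3. The neural stem and progenitor list had a median of -0.35 (0 lower, 4 over the list alone), an adjusted p of 3.58e-05, and adjusted p = 0.12 with an estimated correlation. The cell cycle list had a median of -0.29 (0 by either adjustment), an adjusted p of 4.49e-05, and adjusted p = 0.546 with an estimated correlation. The Notch list had a median of -0.25 (2 lower over the list alone), an adjusted p of 0.00378, and adjusted p = 0.134 with an estimated correlation. The subpallial list had a median of -0.46 (Six3 lower by either adjustment), an adjusted p of 0.00492, and adjusted p = 0.428 with an estimated correlation. The oligodendrocyte lineage list had a median of 0.42 (0 by either adjustment), an adjusted p of 0.0172, and adjusted p = 0.561 with an estimated correlation. The neuron list had a median of -0.23 (0 by either adjustment), an adjusted p of 0.03, and adjusted p = 0.662 with an estimated correlation. The ependymal list had a median of -0.30 (0 by either adjustment), an adjusted p of 0.0365 that became 0.0757 with the sample number as a block, and adjusted p = 0.401 with an estimated correlation. The astrocyte list had a median of -0.14 (1 lower over the list alone), an adjusted p of 0.0464, and adjusted p = 0.662 with an estimated correlation. After quantile normalization the neuron and astrocyte lists did not pass (camera adjusted p = 0.0568 and 0.0697).

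In all, 93 genes passed, 87 higher and 6 lower in neocortex, and 475 (332 higher, 143 lower) with the sample number as a block. The count was 28 and 9 without neocortex samples 2 and 3, and 40, 46 and 40 without striatum samples 1, 2 and 3. With the 9 adult samples alone, chosen after seeing the data, 360 genes passed, including all 93.

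The study design counts transcripts that are at least 2-fold above the other samples in every replicate. Here every sample of a region had to reach 2-fold the mean of each other adult region. By that rule 261 genes marked neocortex spheres, among them 11 of 14 microglia genes such as Csf1r, Trem2 and Itgam, the pallial transcription factors Dmrt3 and Tbr1, and the endothelial genes Cldn5 and Pecam1. The rule sets no minimum signal, so dim genes can meet it. Tbr1 had a mean of 5.75 (log2) in adult spheres and was called present on 6 of 9 adult arrays. It was not among the genes called by limma in neocortex against SVZ. SVZ spheres were marked by 149 genes, among them Hes5, Aqp4, Clu, the growth factor gene Igf2, the reactive glia genes Lcn2, Osmr, Timp1 and Fn1, and the cilia genes Dnali1, Rsph4a and Tekt2, and the endothelial gene Flt1. Striatum spheres were marked by 9 genes, with 0 on any list. All 9 adult samples exceeded the mean of each embryonic forebrain group at least 2-fold in 546 genes, or 1056 without the embryonic samples numbered 1 (chosen after seeing the data), and in 434 genes all 4 embryonic forebrain samples exceeded the mean of each adult group at least 2-fold. In 99 random regroupings of the 9 adult samples a triplet met the rule for a median of 8 genes and at most 344. Among triplets that mixed regions, a restriction chosen after seeing the data, the highest was 98. Without neocortex sample 1 the rule gave 432 genes for neocortex. For striatum it gave 35, 26 and 22 without striatum samples 1, 2 and 3, and 14 without neocortex sample 1 or 3.

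**Figure D3:**
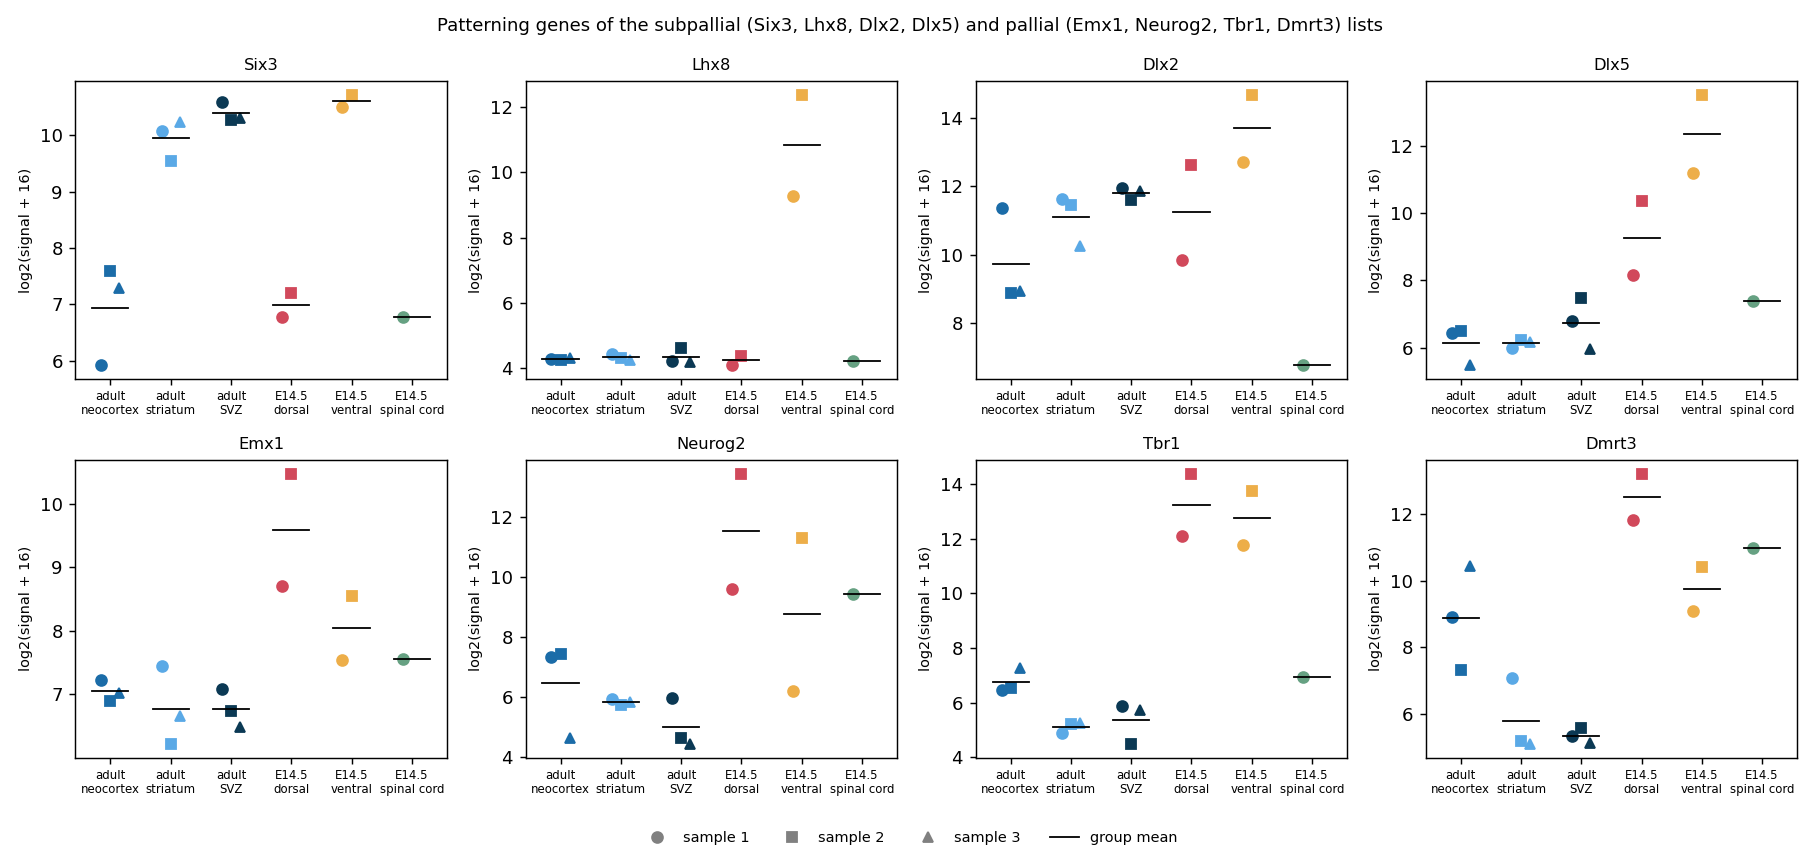
Levels, as log2(signal + 16), of 4 subpallial and 4 pallial patterning genes in each of the 14 samples, with a marker per sample number and a line at each group mean. Six3 lies between 9.54 and 10.60 in the 6 striatum and SVZ samples and between 5.92 and 7.59 in the 3 neocortex samples.

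Dorsal and ventral embryonic forebrain spheres were compared to see which regional genes differ in the embryo. Lhx8, a LIM homeobox gene of the medial ganglionic eminence, was at least 43.1-fold lower in dorsal spheres (limma adjusted p = 0.0277, n = 2 and 2). Its level was 3.10 (log2) higher in ventral sample 2 than in ventral sample 1, so the size of this bound is uncertain. Six3 differed by -3.62 ± 0.48 (log2, SE, adjusted p = 0.0395) and Abat, which breaks down the transmitter GABA, by -2.19 ± 0.30 (adjusted p = 0.0395). Hopx, a homeodomain protein of dorsal radial glia, was higher in dorsal spheres by 3.21 ± 0.44 (adjusted p = 0.0395). In the subpallial list Lhx8 and Six3 were lower (11 of 17 over the list alone), with a median of -2.46, a camera adjusted p of 2.71e-16, and adjusted p = 0.12 with an estimated correlation. In the pallial list 0 of 19 passed over all genes (5 higher over the list alone), with a median of 1.18, an adjusted p of 4.47e-09, and adjusted p = 0.277 with an estimated correlation. The mural and fibroblast list had a median of 1.11 (0 of 15, 1 higher over the list alone), an adjusted p of 0.000591, and adjusted p = 0.433 with an estimated correlation. The sex-linked list had a median of 2.60 (0 of 4, 3 higher over the list alone), an adjusted p of 0.00432, and adjusted p = 0.284 with an estimated correlation. That difference came from ventral sample 2, whose list mean was 7.50 against 11.09 in ventral sample 1 and 11.26 and 11.31 in the dorsal samples. The neuron list had a median of -0.32 (0 by either adjustment), an adjusted p of 0.00823, and adjusted p = 0.567 with an estimated correlation. The astrocyte list had a median of 0.36 (0 of 17, 1 higher over the list alone), an adjusted p of 0.0323, and adjusted p = 0.638 with an estimated correlation. The mural list also separated the samples by number, with sample 2 higher than sample 1 by 3.76 in dorsal and 1.84 in ventral spheres.

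In all, 4 genes passed, 1 higher and 3 lower in dorsal spheres, and 758 had an unadjusted p below 0.05, where 736 would by chance. Same-numbered dorsal and ventral samples deviated together (r of 0.61), which this fit counts as spread. With the sample number as a block 86 genes passed, so the near-chance count does not show that the regions are alike. None of the 4 calls held without each sample in turn. The count was 0 without any of striatum samples 2 and 3 or SVZ samples 1, 2 and 3, which enter only through the shared spread. It was 2 without neocortex or striatum sample 1. It was 60 without dorsal sample 1, 16 without dorsal sample 2 and 124 without ventral sample 1, where the lone sample left is assumed to vary like the other groups. The count was 33 without the samples numbered 2 and the spinal cord, and 208 without those numbered 1, both chosen after seeing the data.

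The last comparison asked whether the difference between neocortex and striatum spheres matched that between dorsal and ventral embryonic spheres. By limma, 0 of 14716 genes differed between the contrasts, with 1027 at an unadjusted p below 0.05 and 736 by chance. With the adult sample numbers as a block, chosen after seeing the data, 1 gene passed, Kndc1 (4.20 ± 0.36, adjusted p = 0.00767), which is named after its value was seen. With the embryonic numbers in the block as well, 144 genes passed. Six3 was lower on the dorsal side in both, by log2 differences of -3.02 ± 0.39 in adult and -3.62 ± 0.48 in embryonic spheres. Across all genes the contrasts, which share no sample, had a Pearson r of 0.0571 and a Spearman rho of -0.0177. Genes are not independent replicates, and this was 1 of 5 such correlations computed. Calls appeared without dorsal sample 1 (24), dorsal sample 2 (17), ventral sample 1 (104) or ventral sample 2 (4). The lists that separated the contrasts with the preset correlation are given in the closing section.

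The spinal cord sample had no replicate, so its differences from the 4 embryonic forebrain samples have no test. Spinal cord spheres carried posterior identity genes. All 8 Hox genes measured, which pattern the body axis behind the forebrain, lay above every forebrain sample and at least 2-fold above their mean. Their median difference was 5.53 (log2), or 5.36 with absent genes at their bound, and the former lay at the 100th percentile of 10000 random lists of the same size. Hoxc10 was at least 193-fold higher and Hoxb4 at least 77.7-fold. Prph, a filament of peripheral and motor neurons, differed by 7.90, Pou4f1, a sensory neuron transcription factor, by 6.67, and the muscle gene Myh3 by 7.50, while Myl1 was at least 76.2-fold higher. Among forebrain transcription factors Tbr1 differed by -6.07 and Dlx2 by -5.71, while Emx2 was at least 41.9-fold and Otx2 at least 13.9-fold lower. Other large differences were those of Lamp5, Mab21l2, Tbx20 and Ppp1r1c, higher, and Nr2e1, Dlx1as, Dlx1, Lhx6, Dmrta2 and Kifc1, lower. In all, 1996 genes were higher and 695 lower by at least 2-fold and outside the forebrain range. The mural and fibroblast list had a median difference of 3.35, the endothelial list 2.30 and the microglia list 1.87, while the cell cycle list had -1.77, with 20 of 23 genes below the forebrain range by at least 2-fold from the mean. The forebrain samples stand apart on the first 3 of these lists. The endothelial list mean was 10.09 in spinal cord, 9.82 and 9.11 in the dorsal and ventral samples numbered 2, and 5.92 and 5.97 in those numbered 1. The microglia list mean was 8.94 in spinal cord, 8.45 and 7.88 in the samples numbered 2, and 5.58 and 5.76 in those numbered 1. The mural and fibroblast list mean was 11.84 in spinal cord, 10.80 and 8.56 in the samples numbered 2, and 7.18 and 6.94 in those numbered 1.

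**Figure D4:**
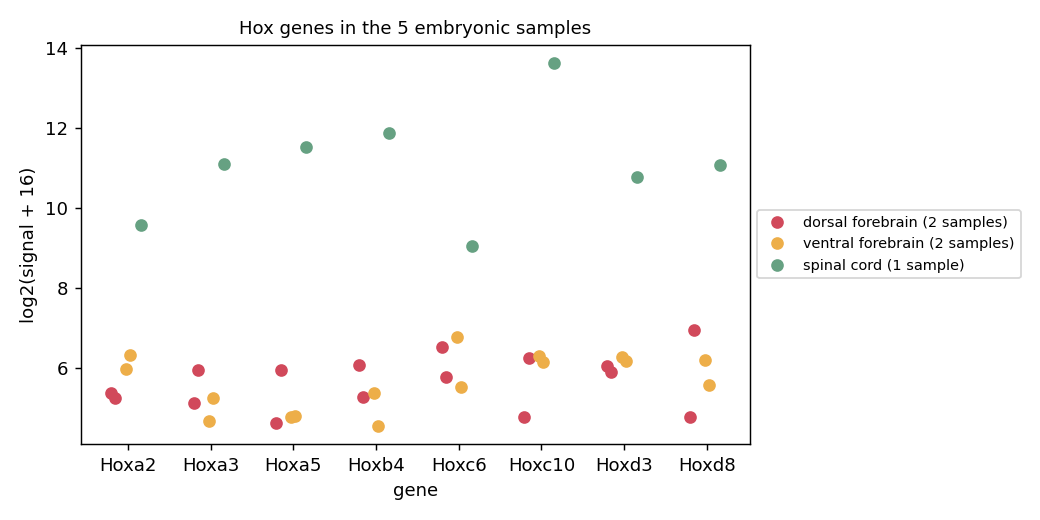
Levels, as log2(signal + 16), of 8 Hox genes in the 5 embryonic samples, a point per sample. The spinal cord sample is the highest for each gene, with 13.64 for Hoxc10 against at most 6.30 in the 4 forebrain samples.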

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

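All tests of explanations in this part were chosen only after the result was seen. The difference between the adult neocortex-striatum contrast and the embryonic dorsal-ventral contrast was planned, and 9 gene lists separated them by camera with the preset correlation, while none did with an estimated correlation.

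By list median the contrast of patterning genes was smaller in adult spheres, but neither an estimated correlation nor fry gave a call. Genes near background can show little contrast. Neurod6, for example, was called present in 0 of 9 adult samples. The pallial list had a median of -0.009 in adult and 1.182 in embryonic spheres, and its median difference was -1.263 (camera adjusted p = 2.72e-05, 0.401 with an estimated correlation, 0.325 by fry). The subpallial list had medians of -0.455 and -2.461, and a median difference of 1.622 (7.06e-05, 0.284 and 0.191 by the same 3 tests). The neural stem and progenitor list differed by -0.645 (5.83e-05, 0.12 and 0.0364) and the Notch list by -0.448 (0.00198, 0.12 and 0.0217). The astrocyte list differed by -0.65 (0.00218, 0.503 and 0.401) and the cell cycle list by -0.469 (0.000585, 0.621 and 0.532). The reactive glia and extracellular matrix list differed by -0.258 (0.0421, 0.294 and 0.237). The mural and fibroblast list differed by -1.105 (0.0298, 0.638 and 0.582). The microglia list differed by 2.49 (7.55e-06, 0.354 and 0.22), with a median of 2.657 in adult and 0.373 in embryonic spheres. The embryonic side rests on 2 samples per region, and no explanation was tested for these differences.

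A pattern weighed after about 5 had been looked at was the distance between the embryonic forebrain samples numbered 2 and those numbered 1. In dorsal spheres 3477 genes and in ventral spheres 3468 genes were at least 2-fold apart, 1723 of them in the same direction in both regions and 169 in opposite directions. Levels of Cldn5, a tight junction gene of vessels, were 11.24 and 10.88 in the samples numbered 2 against 4.64 and 4.84 in those numbered 1. The growth factor receptor gene Egfr went the opposite way, with 7.11 and 8.20 against 12.76 and 13.01. Array scaling alone is argued against, since the smaller endothelial median difference was 3.199 after quantile normalization. Dilution of the progenitors by other cells stays open. The neural stem and progenitor list moved both ways, with upper quartiles of its differences up to 0.651 and lower quartiles of -0.577 (dorsal) and -0.723 (ventral). Vessel cells in the samples numbered 2 also stay open. The endothelial list was higher by at least 3.188 in both regions, but that rise is part of the pattern itself and decides nothing. A different culture age or a different kind of material could not be tested. The sample labels name no difference between these samples. In the second table a dorsal and a ventral embryonic array share a code. The other embryonic arrays, the spinal cord among them, lack it and have codes that end in the letter E. The columns of that table do not name samples, so a difference between preparations stays open. Levels in the spinal cord sample correlated with those in the dorsal and ventral samples numbered 2 with r of 0.9124 and 0.9184. With the samples numbered 1 the values were 0.8678 and 0.8825. No explanation from the groups of the design was tested.

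The next pattern was the higher level of microglia genes in adult neocortex spheres than in SVZ spheres. Abundant members and other myeloid genes were Tyrobp, between 14.12 and 14.65 in neocortex and between 6.91 and 8.48 in SVZ spheres, and Ctss, between 14.34 and 14.98 against 5.57 and 7.95. Array scaling is argued against by a microglia median of 4.665 after quantile normalization. An even fall of all other sphere cells is argued against as the whole cause, since lists of other cells moved apart. The rule for this was written after the list medians were known. The oligodendrocyte lineage list had a median of 1.99 and a lower quartile of 1.16, and the astrocyte list a median of -0.876 and an upper quartile of -0.284. A change in the share of microglia themselves, and so in the total share of the other cells, stays open. Microglia or other myeloid cells carried into the spheres may be a source. The list's members deviated together within groups, with a mean pairwise correlation of 0.199 against a 95th percentile of 0.109 in random lists. Itgam, Cx3cr1, P2ry12 and Tmem119 were not called over all genes, so the kind of myeloid cell stays open. Each of the 14 list genes was called present on at least 2 of the 14 arrays, but the presence filter required this. It therefore does not show detection in the adult spheres. Of these genes 0 are on another list. Region of origin, which the design names, and the way each tissue was dissected and passaged stay open and untested.

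The last pattern weighed was the lower level of cell cycle genes in SVZ spheres than in striatum spheres. Array scaling is argued against by a cell cycle median of 1.331 after quantile normalization. As the whole cause, dividing microglia are argued against only by another pair of regions. From striatum to neocortex the cell cycle list had a median of -0.29, where the microglia list had 2.657. In striatum against SVZ itself both lists were higher, with medians of 1.371 and 1.972. A partial role of dividing microglia therefore stays open. A slower cycle of SVZ spheres, or a later time after passage, may explain the pattern, and neither was tested.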

How the results depend on the processing

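Most alternatives here were planned, and those described as added were tests chosen only after the data had been seen. For 351 gene results, 11050 values were computed under alternatives, of which 11042 kept their direction and 10376 stayed past the threshold.

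Reversed values were confined to 8 in adult against embryonic forebrain. With the spinal cord among the embryonic groups Dlx2 was 0.3136, Nr2e1 1.626 (adjusted p = 2.51e-05) and Rrm2 0.1198. With the block set at the samples numbered 1, an added alternative, Dlx2 was 0.3647, Olig1 -0.04392, Nkx2-2 -0.0436, Cdkn1b 0.07916 and Bcan -0.02128. That coding of the block was the first one run. It compares the groups at the samples numbered 1, and the coding was changed, after its reversals had been seen, to one that compares group means.

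In adult against embryonic forebrain, testing all probe sets gave 14855 calls, since more features were tested. Other settings gave 5265 to 8430 calls, and leaving out 1 sample gave 5924 to 7484. For neocortex against SVZ the counts were 3240 with all probe sets, 3192 with array weights, 3210 with only the groups compared and 3672 with the sample number as a block. Added alternatives gave 3358 without embryonic samples 2 and the spinal cord, 3357 without embryonic samples 1, 3348 with adult samples only and 3850 with a block over them. For striatum against SVZ the same 8 settings gave 975, 2907, 1463, 1894, 1545, 1531, 1543 and 2081. For neocortex against striatum they gave 159, 342, 245, 475, 360, 357, 360 and 642, with 45 at a pseudocount of 1 and 155 at 64. Leaving out 1 sample gave 1043 to 2272 for neocortex against SVZ, 84 to 810 for striatum against SVZ and 9 to 136 for neocortex against striatum. Apart from the tests of all probe sets, the cause was not tested, and the added fits were not used to replace the planned counts.

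For dorsal against ventral forebrain the counts were 13 at a pseudocount of 64, 9 with median centring, 2 with the mean of all probe sets, 0 with array weights, 0 with only the groups compared (limma) and 86 with the block. They were 33 and 208 without the embryonic samples 2 and 1, and 0 to 124 without 1 sample. The difference of contrasts gave 24 at a pseudocount of 64, 144 with the block, 1 with a replicate block for the adult numbers only (added), 54 and 206 without the embryonic samples 2 and 1, and 0 to 104 without 1 sample. The cause was not tested. The deviations of same-numbered samples of the 2 embryonic regions had an r of 0.61, a single value since 2 samples per group deviate oppositely, and the block takes this up. With median centring the median of all genes moved from -0.0154 to -0.129 in the difference of contrasts.

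Of 51 list calls 0 held with an estimated correlation, while 30 list tests passed with fry, 48 after quantile normalization and 52 with the block. With the block the MHC class I and interferon list passed in neocortex against SVZ (adjusted p = 0.0248, 0.0517 before) and the oligodendrocyte lineage list in the difference of contrasts (0.0225, 0.508 before). After quantile normalization the list calls of neural stem (0.0773) and reactive glia (0.0632) in striatum against SVZ, and of astrocyte (0.0697) and neuron (0.0568) in neocortex against striatum, were lost. There the MHC class I and interferon list passed in neocortex against SVZ (0.0492).

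With the fold rule at 1.5-fold and 3-fold, neocortex had 449 and 152 genes, striatum 45 and 2, SVZ 387 and 31, and adult over embryonic 1066 and 232. Without a presence filter striatum had 26, and without embryonic samples 1 adult over embryonic had 1056. Leaving out 1 sample gave 244 to 432 in neocortex, 11 to 35 in striatum and 130 to 209 in SVZ. The spinal cord count of 2691 was 2612 after quantile normalization and 3372 without a filter.

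The other deposited table was not run as an alternative, because its columns match groups and not samples. Signals close to background limit the values of dim genes.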

Other observations

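The tests of own hypotheses in this part were chosen only after the result was seen, and the splits of samples were planned.

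For the 3 adult comparisons the 6 samples allow 10 splits, so the share of splits with as many genes cannot go below 0.1. The real counts were 1852 for neocortex against SVZ, 608 for striatum against SVZ and 93 for neocortex against striatum. In each, only 1 of 10 splits, the real one, reached its count, and the highest of the others was 0. For adult against embryonic forebrain a 2-group fit called 6686 genes. Of 100 splits drawn from 715, only 1, the real one, reached that count, and the highest other was 1383. The splits treat the 13 samples as independent, while same-numbered dorsal and ventral embryonic samples deviated together (r of 0.61). If such samples share a preparation, these splits cannot exclude chance.

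A hypothesis was that spheres keep the patterning of their region. Across 36 patterning genes the adult neocortex minus striatum difference had a Pearson r of 0.462 with the embryonic dorsal minus ventral difference, with a Spearman rho of 0.468. This lay at the 97.09th percentile of 10000 random gene sets, and at the 93.84th without Six3 (r 0.406). Both missed the percentile required of them, so the hypothesis was not supported, which does not show that patterning is lost. It was 1 of 5 correlations across genes, and genes are not independent replicates. The others were 0.0571 over all genes, 0.519 over the 93 called genes (Spearman rho 0.0917), and 0.012 over all genes and 0.443 over patterning genes with neocortex minus SVZ.

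A further hypothesis was that interferon genes differ by sample number in a way shared by neocortex and striatum. Ifit1, an interferon-induced gene, had levels of 10.85, 8.14 and 4.43 in neocortex samples 1, 2 and 3, and of 11.83, 8.08 and 4.70 in striatum. Across the list the deviations correlated with r of 0.871, 0.22 and 0.798 for numbers 1, 2 and 3, where more than 0.5 was required of each, so the hypothesis did not meet its bar. The list's deviations were smaller for number 2 (root mean square 0.415 in neocortex and 0.518 in striatum) than for number 1 (1.14 and 1.47) and number 3 (1.1 and 1.19). The list means of numbers 1, 2 and 3 were 10.37, 9.59 and 9.21 in neocortex, 10.84, 9.45 and 9.18 in striatum, and 10.91, 10.56 and 10.16 in SVZ. With SVZ samples the values for neocortex were 0.132, 0.343 and 0.736.

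Sex-linked genes showed the makeup of the samples. Xist was between 4.19 and 6.53 in the 9 adult samples, in which the Y-linked gene Eif2s3y was between 13.29 and 13.55. In the 5 embryonic samples Xist was between 12.72 and 14.04. Eif2s3y was between 11.79 and 12.29 in 4 of them and 6.14 in ventral sample 2, where Kdm5d was 5.47 and Uty 4.34. By these genes the 9 adult samples looked male and ventral sample 2 female, while the other embryonic samples carried both signals. Sex makeup and age therefore cannot be told apart in adult against embryonic forebrain.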
